A study of Mus musculus with 10 samples.

How the data were processed

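RNA was measured by sequencing in whole kidneys of wild-type mice on day 14, 5 given vehicle and 5 given quinolinic acid at 0.5 g/L in drinking water, and samples were grouped by the treatment in their labels. Per the submitters' processing notes, the tools were FastQC 0.11.2, STAR 2.5.3a, featureCounts from Subread 1.4.6 and edgeR, on genome build mm10. The annotation release, filters, strand setting and library depths were not given in the sources used here. Per the file header and name, the values are the output of edgeR's likelihood-ratio test by the authors for each GENCODE transcript, vehicle versus quinolinic acid.

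The authors' log2 fold change and mean log2 CPM, deposited for 85107 transcripts, were used as they stand. The mean CPM values summed to 1003340, which shows base 2. The authors' likelihood-ratio statistic is a score on 1 degree of freedom. The deposited p-value equalled the chi-square tail of that score, and the deposited adjusted p equalled the Benjamini-Hochberg value over all transcripts, to within rounding. The header does not say which group is the numerator of the fold change, so signs are reported as deposited, with no direction relative to quinolinic acid.

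A test on counts or values of each library had been chosen before the data were examined. The values used here are a finished comparison, so the authors' likelihood-ratio test took its place, and a transcript was called at a deposited adjusted p under 0.05. Without values per library the precision behind each value comes only from the deposited statistics. An approximate standard error was taken as the absolute log2 fold change divided by the square root of the likelihood ratio, and the 95% interval from it. It covers what the authors' model covers and cannot show how single mice differ.

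Transcripts were matched by identifier without version to GENCODE vM21 (GRCm38, the assembly of mm10). Of them 83446 (98.0%) matched, 1661 did not, and 49.9% had the same version number. Coordinates are those of the gene's most abundant transcript in vM21. Each of 27876 gene symbols was represented by its transcript with the highest mean CPM. For 13158 genes the table held more than 1 transcript, and 20.5% of the further transcripts lay within 0.01 of the log2 fold change of the most abundant one. Sums of near-identical values were therefore avoided in all gene lists.

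Before the data were examined, 50 gene lists were fixed, with 26 pathways, 23 cell types or neighbouring tissues and 1 check list of sex-linked and sex-biased genes. Lists were tested with preranked camera (limma 3.58.1 in R 4.3.3) on the signed square root of the likelihood ratio, two-sided, with an assumed correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 50 lists. Camera compares the members with all other genes. Medians were also set against 10000 random lists matched on mean level, and on level and transcript length. Trends were removed with loess (span 0.5) on log2 length and mean level, and also on GC content. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the other computations, and matplotlib 3.10.9 the figures.

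The genes named were chosen by a rule fixed in advance. Among called genes of at least 1 CPM, leaving out gene models without a proper name and pseudogenes, the 12 with the largest log2 fold change of each sign were to be named. Where fewer than 5 passed in a direction, the 5 with the smallest p in that direction were named instead. All kynurenine pathway members, Havcr1 and Lcn2 were named in any case. Each called list gave up to 4 members with the smallest p in its direction, and each other list described gave up to 2. Genes named outside the rule are said to be so, and a few genes that the rule would name are not reported here.

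The list test and the recovery of single genes were tested on simulated data. For vehicle versus quinolinic acid, with 27876 genes, 73.5% of 200 lists of 25 genes shifted by 0.8 standard units were recovered, and 0.1% of unshifted lists were called. The simulated genes were independent and had no trend with length, so 0.1% is not the false-call rate of the lists called here. With changes given to 200 of 13115 genes of at least 1 CPM at their approximate errors, and adjustment over those genes alone, 48.4% of genes changed by 0.5 on the log2 scale were recovered, 94.3% of those changed by 1 and 99.7% of those changed by 2. The deposited adjustment covers 85107 transcripts and so asks for larger changes than this simulation, which does not give the recovery of the authors' test. The alternatives tried were other thresholds, a filter at 1 CPM, protein-coding transcripts, 1 transcript per gene, the removal of trends, ranks, and other assumed correlations.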

Results

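The series measured RNA in whole kidneys of wild-type mice. Quinolinic acid, a product of tryptophan breakdown through the kynurenine pathway and an agonist of NMDA-type glutamate receptors, was given in the drinking water at 0.5 g/L, and the other group received vehicle. Kidneys were taken on day 14 from 5 mice per group, which gave 10 libraries under 1 batch label. The comparison asks which kidney transcripts differ between mice exposed to quinolinic acid and mice given vehicle. The labels do not say whether kidney injury was induced in these animals.

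The values came from the authors' deposited table, which holds 85107 transcripts with a log2 fold change, a mean log2 CPM over the libraries, a likelihood-ratio statistic, a p-value and an adjusted p for vehicle versus quinolinic acid. Counts of single libraries were not analysed here, so the depth of each library is unknown and no spread between mice can be given. Errors are therefore approximate 95% intervals, computed from the deposited fold change and likelihood ratio and printed for genes of at least 1 CPM. The header does not say which group is the numerator of the fold change. Signs are given below as deposited, and whether a positive sign means more or less RNA after quinolinic acid is left open throughout.

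Few transcripts differed between the groups. An adjusted p under 0.05 was reached by 12 transcripts of 6 genes in the authors' deposited table, 9 with a positive and 3 with a negative sign. The genes with a positive sign were Dusp1, a phosphatase that switches off MAP kinases, Gadd45g, a stress-inducible growth arrest gene, Cldn11, a tight junction claudin, and Gls2, the liver-type glutaminase. Those with a negative sign were Ighg2b, the constant region of the IgG2b heavy chain, and Scgb1a1, a secretoglobin best known from airway club cells. At an unadjusted p under 0.05 the authors' deposited table held 5176 transcripts (6.08%), 2437 positive and 2739 negative. By mean level this share was 5.90% under 0.1 CPM, 9.62% from 0.1 to 1 CPM and 5.50% from 1 to 10 CPM. It was 3.61% from 10 to 100 CPM and 1.15% at 100 CPM or more. Cldn11, Gls2 and Ighg2b lay from 0.1 to 1 CPM, where the share was highest. Transcripts of a gene share reads, so the 12 transcripts are not independent measurements.

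Of these 6 genes, only Dusp1 and Gadd45g reached a mean of 1 CPM. Dusp1 (chromosome 17, 26505591 to 26508474, mm10) had a log2 fold change of 0.83 (95% interval 0.55 to 1.11), a 1.78-fold difference at 15.1 CPM, with an adjusted p of 0.000283 in the authors' deposited table. The transcript behind this value is annotated as retaining an intron, and the coding Dusp1 transcript had the same rounded log2 fold change, 0.83, in the authors' deposited table. Gadd45g (chromosome 13, 51846678 to 51848468) had a log2 fold change of 1.20 (95% interval 0.71 to 1.69), a 2.30-fold difference at 16.2 CPM, with an adjusted p of 0.0217 in the authors' deposited table. With the trend of fold change on transcript length and level removed, its log2 fold change was 1.04 and its adjusted p 0.246.

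The other 4 genes, named because the count is small and chosen after their values were seen, were measured at under 1 CPM. According to the authors' deposited table, Cldn11 (chromosome 3, 31149920 to 31164324) had a log2 fold change of 2.26 at 0.209 CPM and an adjusted p of 0.0217. For Gls2 (chromosome 10, 128194726 to 128210004) the authors' deposited table called 4 transcripts, with log2 fold changes of 1.68 to 1.73 at about 0.20 CPM. The 3' end of Gls2 overlaps Spryd4 on the opposite strand, and whether the counting used strand is not given in the sources used here. With the length and level trend removed, Cldn11 and Gls2 kept log2 fold changes of 2.15 and 1.58, and the adjusted p of both was 0.0660. Ighg2b (chromosome 12, 113306285 to 113307933) had a log2 fold change of -4.66 at 0.363 CPM and an adjusted p of 0.00644 in the authors' deposited table. IgG constant regions resemble each other closely, so its reads can be shared with them and the value is uncertain. Scgb1a1 (chromosome 19, 9083636 to 9087958) had a log2 fold change of -2.95 at 0.0723 CPM and an adjusted p of 0.0217 in the authors' deposited table.

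**Figure D1:**
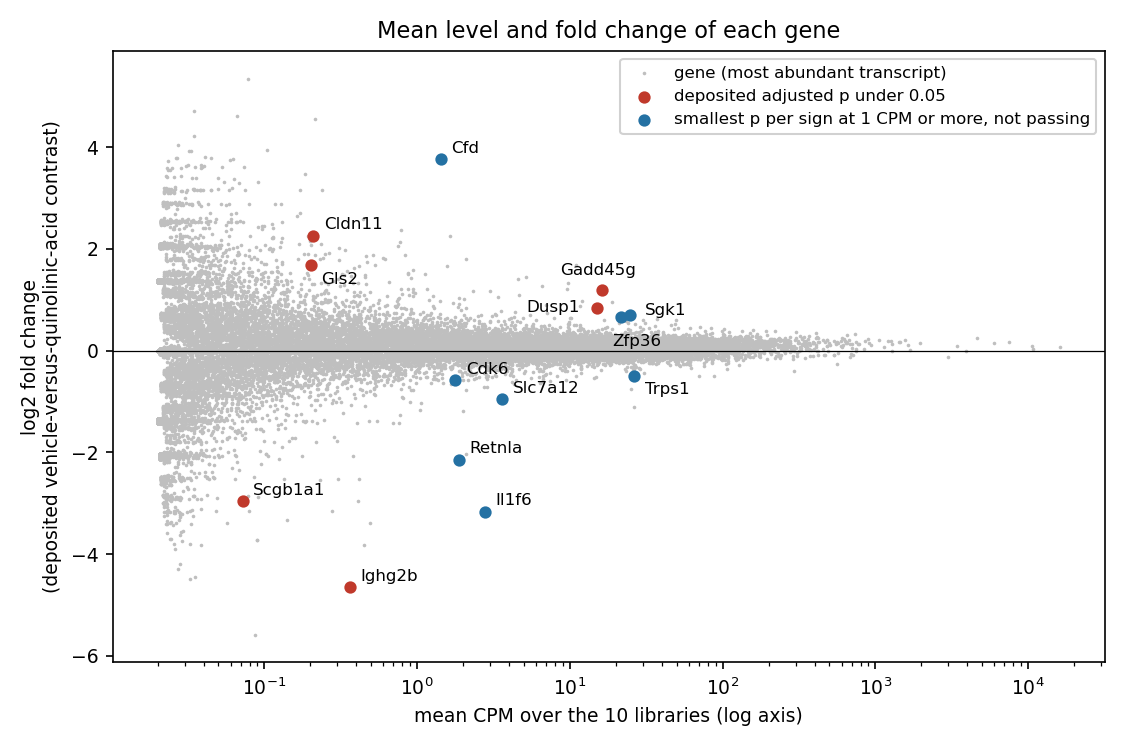
Mean CPM over the 10 libraries (horizontal log axis) against the log2 fold change of the deposited contrast (vertical axis) for the most abundant transcript of each gene. Red points are the 6 genes with a deposited adjusted p under 0.05 and blue points are the genes of at least 1 CPM with the smallest p of each sign that did not pass. Dusp1 and Gadd45g are the red points above 1 CPM, at log2 fold changes of 0.83 and 1.20.

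Most expressed genes differed little. Among 13115 genes of at least 1 CPM, 98.5% had a log2 fold change within 0.5 of 0 and 71.8% had a positive sign, with a median of 0.08. Beyond Dusp1 and Gadd45g, the genes of at least 1 CPM with the smallest p on the positive side did not pass. They were Cfd, which encodes complement factor D (adipsin), at a log2 fold change of 3.77, Zfp36, which promotes decay of cytokine mRNA, at 0.67, and the serum- and glucocorticoid-regulated kinase Sgk1 at 0.69 in the authors' deposited table. Their adjusted p in the authors' deposited table was 0.112, 0.112 and 0.145. No gene of at least 1 CPM passed with a negative sign in the authors' likelihood-ratio test, while 116 such genes had a negative sign at an unadjusted p under 0.05 against 420 with a positive sign. The smallest p among them belonged, in the authors' deposited table, to the transcription repressor Trps1 (log2 fold change -0.49, adjusted p 0.163), the interleukin-36 gene Il1f6 (-3.17, 0.359), the amino acid transporter Slc7a12 (-0.95, 0.359), the cell cycle kinase Cdk6 (-0.58, 0.392) and the resistin-like gene Retnla (-2.14, 0.422).

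No gene of the kynurenine pathway, in which quinolinic acid is made and consumed, passed the test over all transcripts. Of the 12 members measured, 7 had a positive and 5 a negative sign, with a median log2 fold change of 0.07. The list was not called against the other genes (camera adjusted p = 0.552). Qprt, which converts quinolinic acid towards NAD, had a log2 fold change of 0.10 (95% interval -0.20 to 0.39, 33.2 CPM) in the authors' deposited table. Acmsd, the enzyme that diverts the pathway away from quinolinic acid, stood at -0.23 (-0.76 to 0.31) and Haao, which makes its precursor, at 0.00 (-0.59 to 0.59) in the authors' deposited table. Kynu, kynureninase, had a log2 fold change of 0.69 (0.29 to 1.09) at 2.61 CPM, with p = 0.0007 and an adjusted p of 0.368 in the authors' deposited table. Kynu was the 1 member with an adjusted p under 0.05 (0.00840) when adjusted over the list alone.

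Transcripts of Tdo2 and Ido1, which can start the pathway, were scarce. Tdo2 had a log2 fold change of 1.98 at 0.0930 CPM (p = 0.0149, adjusted p 0.765) and Ido1 one of -0.21 at 0.0565 CPM in the authors' deposited table. The remaining log2 fold changes in the authors' deposited table were 0.24 for Ido2, -0.01 for Afmid, 0.05 for Kmo, 0.14 for Kyat1, -0.09 for Aadat and 0.09 for Kyat3, and each approximate interval included 0. Of 23 genes of NAD salvage and consumption, 18 had a positive sign, with a median of 0.12 and a camera adjusted p of 0.108. Their smallest p belonged to the sirtuin Sirt5 (0.30) and the NAD hydrolase Cd38 (0.42), with adjusted p of 0.794 for both in the authors' deposited table. The 17 measured NMDA and glutamate receptor and transporter genes had a median of 0.03 and a camera adjusted p of 0.831. Grin1, the obligate NMDA receptor subunit, was measured at only 0.0608 CPM in the authors' deposited table.

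**Figure D2:**
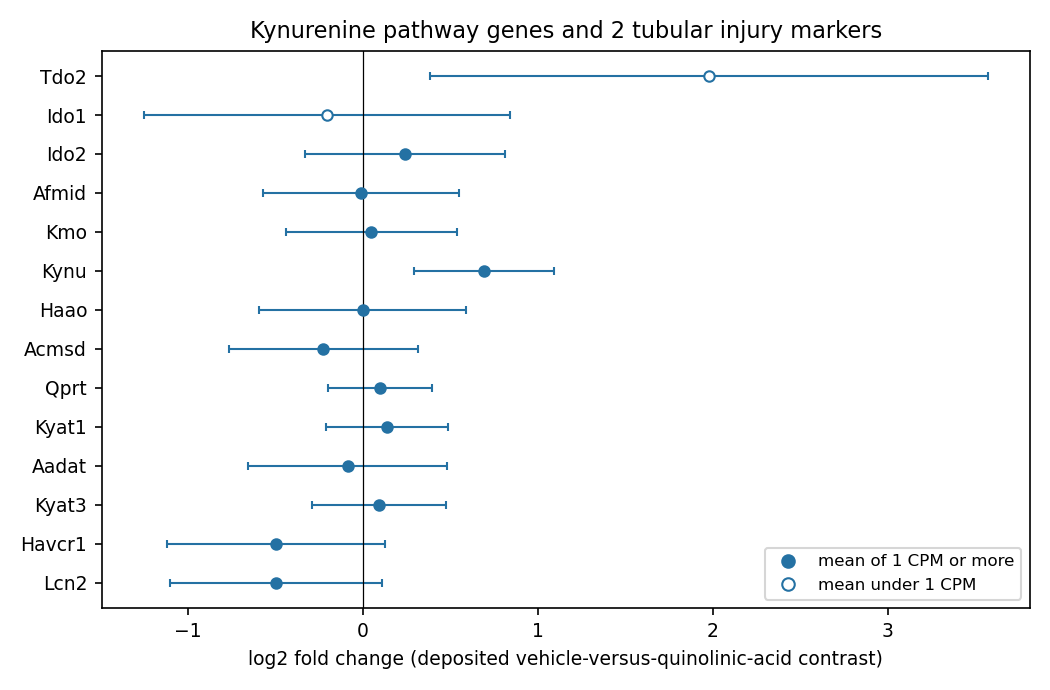
Log2 fold change of the deposited contrast (horizontal axis) for the 12 kynurenine pathway genes and the tubular injury markers Havcr1 and Lcn2, with approximate 95% intervals as bars. Open points are genes under 1 CPM, whose intervals are rough. The interval of Kynu, 0.29 to 1.09, and that of Tdo2 exclude 0, but neither passed the adjustment over all transcripts.

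Markers of tubular injury were not called as a group. The contrast concerns a difference between the groups and does not show whether the kidneys of both were injured. Havcr1, which encodes kidney injury molecule 1, had a log2 fold change of -0.50 (95% interval -1.12 to 0.12) at 88.1 CPM in the authors' deposited table. Lcn2, the gene of neutrophil gelatinase-associated lipocalin, had one of -0.50 (-1.10 to 0.11) at 69.5 CPM, with an adjusted p of 0.794 for both in the authors' deposited table. Of the 23 members of the injury list 15 had a positive sign, with a median of 0.12 and a camera adjusted p of 0.796. The fibrinogen gene Fgb (1.05, p = 0.00223) and the intermediate filament gene Vim (0.36, p = 0.0151) had its smallest p in the authors' deposited table. Fgb is also among the liver genes described below. The 31 extracellular matrix genes had a median of 0.05 (camera adjusted p = 0.903), and Ccn2 (0.32) and Dcn (0.25) had the smallest p among them in the authors' deposited table. The 27 inflammatory genes had a median of 0.03 and a mean of 0.01, while camera, which compares them with all other genes, gave a negative direction (adjusted p = 0.798). The 28 interferon response genes had a median of 0.14 (camera adjusted p = 0.345).

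Across the 50 gene lists, camera called 10, all with a positive direction and none with a negative one. At an unadjusted p under 0.05 the counts were 15 positive and 1 negative. The test assumed a correlation of 0.01 between genes, and the correlation could not be estimated without values per library. With an assumed correlation of 0.05 camera called 7 lists, and with 0.1 it called 2, those of adipocyte and liver genes.

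Immediate early genes, which respond to stimuli within minutes, leaned to the positive side together with Dusp1. Of 27 measured, 23 had a positive sign, with a median log2 fold change of 0.30 (camera adjusted p = 1.15e-05). After Dusp1, the smallest p belonged to Zfp36 (0.67), Myc (0.90, p = 0.000193) and Fos (1.10, p = 0.00216) in the authors' deposited table. Over all transcripts only Dusp1 passed, and 4 members passed when adjusted over the list alone. The camera adjusted p was 0.00466 with an assumed correlation of 0.05 and 0.0613 with 0.1.

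Circadian clock genes went in both directions. Of 19 measured, 14 had a positive sign, with a median of 0.19 (camera adjusted p = 0.0212). Positive members with a small p in the authors' deposited table included Nfil3 (1.18, p = 0.000930), Cry1 (0.69, p = 0.00308) and Per2 (0.50, p = 0.00503). Arntl, which encodes the clock activator BMAL1, had a log2 fold change of -0.77 and its partner Clock one of -0.27 in the authors' deposited table, and both were singled out after their values were seen. None passed over all transcripts, while 5 positive and 2 negative members passed when adjusted over the list alone. The list's call ended with an assumed correlation of 0.05 (adjusted p = 0.134), with ranks (0.0710), among genes of at least 1 CPM (0.111), with the coding transcript of each gene (0.0762) and with the length, level and GC trend removed (0.0533).

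Genes of fat and liver had the largest differences among the lists. Of 14 adipocyte genes, 12 had a positive sign, with a median log2 fold change of 1.82 (camera adjusted p = 3.09e-09). In the authors' deposited table the log2 fold change was 4.55 for the adipokine gene Adipoq, 3.77 for Cfd, 4.61 for the lipid droplet gene Plin1 and 3.48 for Ucp1, the uncoupling protein of brown fat. Their levels in the authors' deposited table were low, at 0.216, 1.43, 0.0660 and 0.184 CPM. The adipocyte genes Fabp4 (0.19 at 21.7 CPM) and Car3 (-0.06 at 13.7 CPM) stood higher in these kidneys and moved little in the authors' deposited table. Both were picked after their values were seen and do not stand for all adipocyte genes of higher level. No adipocyte gene passed over all transcripts, and 8 passed when adjusted over the list alone. Among genes of at least 1 CPM, of which the list has 6, the call ended (adjusted p = 0.305).

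Of 12 liver genes, 11 had a positive sign, with a median of 1.13 (camera adjusted p = 1.64e-06). In the authors' deposited table the smallest p belonged to Fgb (1.05, 3.37 CPM), the fetuin gene Ahsg (1.98, 0.335 CPM), the albumin gene Alb (1.27, 6.53 CPM) and the apolipoprotein gene Apoa1 (1.20, 0.782 CPM). None passed over all transcripts, and 6 passed when adjusted over the list alone. The 11 nervous tissue genes all had a positive sign, with a median of 0.47 (camera adjusted p = 0.00880), led in the authors' deposited table by Sox10 (1.17), Tubb3 (1.68), Snap25 (2.29) and S100b (0.69). The 13 urothelial genes, which mark the lining of the renal pelvis, all had a positive sign, with a median of 0.58 (camera adjusted p = 0.0164). They were led by Psca (1.08), Upk1a (0.50), Upk1b (0.87) and Upk3a (0.84) in the authors' deposited table. No nervous tissue or urothelial gene passed over all transcripts or when adjusted over its list alone. The nervous tissue call ended with an assumed correlation of 0.1 (adjusted p = 0.122) and could not be tested among genes of at least 1 CPM, where 4 members were left. The urothelial call ended with an assumed correlation of 0.05 (0.0739) and with the length, level and GC trend removed (0.0706), and only 3 members reached 1 CPM. With the length and level trend removed the urothelial median was 0.45 and the call ended narrowly (adjusted p = 0.05001).

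**Figure D3:**
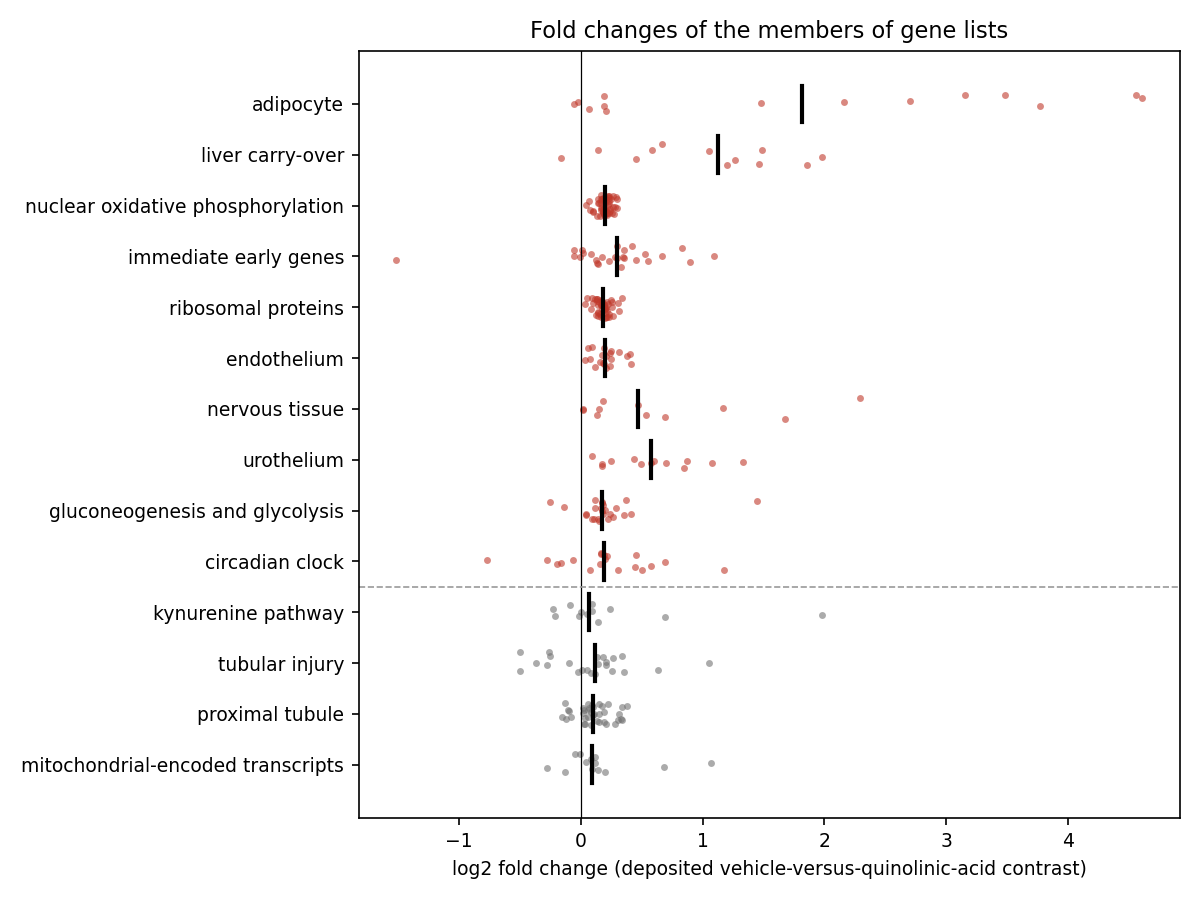
Log2 fold change of the deposited contrast (horizontal axis) for each measured member of the 10 called gene lists (red, above the dashed line) and of 4 lists that were not called (grey). Each point is a gene and the black bar is the list's median, which is 1.82 for adipocyte genes, 1.13 for liver genes and 0.07 for the kynurenine pathway.

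Genes of energy metabolism and of the ribosome shared a small positive sign. All 56 nuclear genes of oxidative phosphorylation had a positive sign, with a median log2 fold change of 0.20 and a middle 50% from 0.17 to 0.23 (camera adjusted p = 2.27e-06). Their smallest p in the authors' deposited table belonged to Cox8a (0.29), Cox5a (0.28), Cox6a1 (0.30) and Ndufs7 (0.27). All 49 ribosomal protein genes had a positive sign, with a median of 0.18 and a middle 50% from 0.14 to 0.22 (camera adjusted p = 2.37e-05). They were led by Rps12 (0.31), Rpl30 (0.26), Rplp2 (0.34) and Rpl6 (0.19) in the authors' deposited table. Processed copies of ribosomal protein genes are common in the genome, so reads can be shared with them. None of these genes passed over all transcripts or when adjusted over its list alone. Of 25 genes of gluconeogenesis and glycolysis, 23 had a positive sign, with a median of 0.18 (camera adjusted p = 0.0204). Members with a small p in the authors' deposited table included Fbp2 (0.42), Pdk1 (0.27) and Eno1 (0.24), and no member of the list passed either adjustment. The 13 transcripts encoded in mitochondrial DNA had a median of 0.09 and a mean of 0.16, while camera gave a negative direction (adjusted p = 0.903), and 4 of them were measured at under 1 CPM.

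The fold change followed transcript length. Across 11638 coding genes of at least 1 CPM, Spearman's rho between log2 fold change and length was -0.53, a value across genes, which are not independent replicates. The median log2 fold change was 0.19 for transcripts under 1000 nt, of which 94.6% had a positive sign, and -0.05 for transcripts of 6000 nt or more, of which 30.6% did. With the trend on length and level removed, the median of the oxidative phosphorylation genes was 0.04 (camera adjusted p = 0.613), that of the ribosomal protein genes 0.02 (0.724) and that of gluconeogenesis and glycolysis 0.07 (0.281), so that these 3 calls ended. The gluconeogenesis and glycolysis call also ended with an assumed correlation of 0.05 (0.146), among genes of at least 1 CPM (0.208) and with the coding transcript of each gene (0.101). With 0.1 the adjusted p was 0.106 for oxidative phosphorylation and 0.122 for ribosomal proteins.

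**Figure D4:**
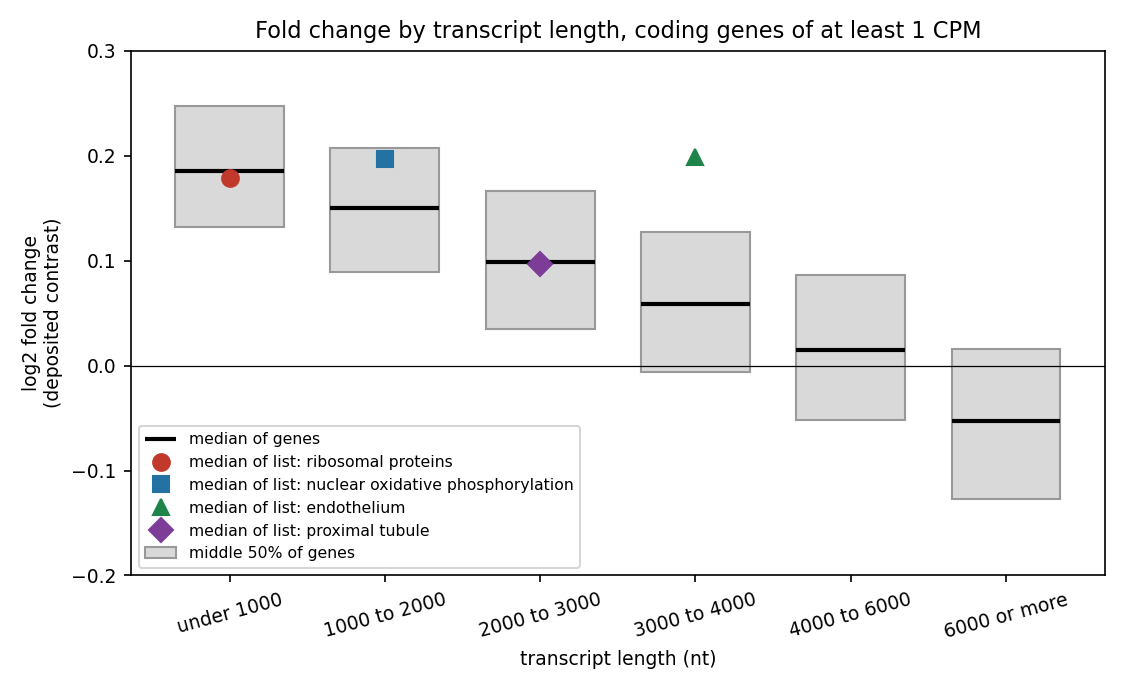
Log2 fold change of the deposited contrast (vertical axis) for coding genes of at least 1 CPM in bins of transcript length (horizontal axis, nt), with the median as a black line and the middle 50% of genes as a grey box. Coloured symbols are the medians of 4 gene lists, placed in the bin of their median transcript length. The medians run from 0.19 under 1000 nt to -0.05 at 6000 nt or more, and ribosomal protein genes (0.18) lie near the median of their bin while endothelial genes (0.20) lie above theirs.

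Among the lists of kidney cell types, camera called those of endothelium and, as given above, urothelium. All 20 endothelial genes had a positive sign, with a median of 0.20 (camera adjusted p = 0.000554), led in the authors' deposited table by Plat, tissue plasminogen activator (0.42), the transcription factor Sox17 (0.38), Esam (0.24) and Emcn (0.25). None passed over all transcripts or when adjusted over the list alone. With the length and level trend removed the endothelial median was 0.12 and the call stayed (adjusted p = 0.00407), and with an assumed correlation of 0.1 it ended (0.106). The 14 podocyte genes had a median of 0.13 (camera adjusted p = 0.0538), and this list was called with the length and level trend removed (0.0327). Cdkn1c had its smallest p in the authors' deposited table (0.56, p = 0.00108) and passed when adjusted over the list alone. The 38 proximal tubule genes had a median of 0.10 (camera adjusted p = 0.619), led by the sulfate transporter Slc13a1 (0.33) and the amino acid transporter Slc7a9 (0.31) in the authors' deposited table. Of the 13 thick ascending limb genes 10 had a negative sign, with a median of -0.04 (camera adjusted p = 0.467). The 28 macrophage and monocyte genes had a median of 0.08 (camera adjusted p = 0.394), with Trem2 at 1.45 (p = 0.00196) in the authors' deposited table. The 24 T and NK cell genes had a median of 0.08, while camera gave a negative direction (adjusted p = 0.951). The 16 neutrophil genes had a median of 0.00 and a mean of 0.31, while camera gave a negative direction (adjusted p = 0.796), which passed among genes of at least 1 CPM (0.0138), where only 5 members were left.

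Several stress and signalling lists were not called. The 31 targets of NRF2, the regulator of the oxidative stress response, had a median of 0.09 (camera adjusted p = 0.254). The glutathione transferase genes Gsta4 (0.47, p = 0.00131) and Gsta2 (0.47, p = 0.00497) had the smallest p in the authors' deposited table, and Gsta4 passed when adjusted over the list alone. The 31 genes of fatty acid oxidation and PPAR-alpha had a median of 0.12 (camera adjusted p = 0.254), led in the authors' deposited table by Fabp1 (1.83 at 0.596 CPM), which passed when adjusted over the list alone, and Acaa1a (0.28). The 11 targets of the aryl hydrocarbon receptor, a receptor for tryptophan metabolites, had a median of 0.18 (camera adjusted p = 0.131). Aldh1a3 (1.59 at 0.946 CPM, p = 0.000557) passed when adjusted over that list alone, and Cyp1a2 (1.42 at 0.0509 CPM) did not, by the authors' deposited table. The 13 renin-angiotensin genes had a median of 0.14 (camera adjusted p = 0.131), with Sgk1 (0.69) and the renin gene Ren1 (0.61, p = 0.0107) first in the authors' deposited table, and Sgk1 passed when adjusted over the list alone. The 18 sex-linked and sex-biased kidney genes split into 9 positive and 9 negative, with a median of -0.01 and a camera adjusted p of 0.115 in the negative direction. That list was called among genes of at least 1 CPM (0.00818), with the coding transcript of each gene (0.0335) and with the length and level trend removed (0.0172). It mixes Xist, expressed in females, with Y-linked genes such as Ddx3y. A shared direction of the list therefore cannot show or exclude a difference in sex between the groups. Slc7a12 (-0.95) and Cyp4a14 (-1.11) had the list's smallest p in the authors' deposited table, and Slc7a12 passed when adjusted over the list alone.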

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

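Every alternative here was chosen after the data were seen, except the adjusted p under 0.1 and the minimum log2 fold change of 1. Against 12 called transcripts of 6 genes, an adjusted p under 0.1 gave 22 transcripts of 14 genes, transcripts of at least 1 CPM gave 4 of 2 genes, and protein-coding transcripts gave 5 of 5 genes. A minimum log2 fold change of 1 gave 10 transcripts of 5 genes, 1 transcript per gene called 8 genes, and the same with the length and level trend removed called 3, Dusp1, Ighg2b and Scgb1a1. Against 10 called lists, 2 were called with an assumed correlation of 0.1 and 5 with the length, level and GC trend removed, all among the 10. The other settings called 7 with a correlation of 0.05 and 9 with ranks, all among the 10, 9 with coding transcripts (8 of them among the 10), 7 at 1 CPM or more (5 among the 10, and 2 others with a negative direction) and 8 with the length and level trend removed (6 among the 10). Immediate early and endothelial genes were called under each setting except the correlation of 0.1, and liver genes under all 7. The camera direction turned, never with a call, for tubular injury (adjusted p 0.944 at 1 CPM or more, 0.996 with coding transcripts, 0.408 without the length and level trend, 0.662 also without GC), extracellular matrix (0.703 at 1 CPM or more, 0.887 with coding transcripts, 0.881 without length, level and GC trend) and glutamate receptors (0.703 at 1 CPM or more, 0.970 with coding transcripts). It also turned with trends removed for proximal tubule (0.784 and, with GC, 0.743, and 0.976 at 1 CPM or more), macrophages (0.864 and 0.937), NRF2 targets (0.864 and 0.931) and fatty acid oxidation (0.875). Kmo and Qprt turned to log2 fold changes of -0.0025 and -0.024 with the length and level trend removed, both far inside their intervals. The cause of these changes was not tested, except that the filters test fewer transcripts. No paired analysis was possible because the values describe a finished comparison and no single kidney. For the same reason, settings chosen before the data were examined that need values per kidney were not run. These were RLE, upper-quartile and total-count scaling, count filters, DESeq2, quasi-likelihood and voom tests, other dispersion settings, another pseudocount, an estimated correlation, fry, and leaving out each kidney, and other splits of the 10 kidneys could not be counted. Level limits what could be called. The median approximate error would need a log2 fold change of 4.82 under 0.1 CPM, 1.42 from 0.1 to 1 CPM, 0.81 from 1 to 10 CPM, 0.61 from 10 to 100 CPM and 0.81 at 100 CPM or more.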

Other observations

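The tests here were set up after the results of the fixed gene lists had been seen. For the second lists of fat and liver genes, the glucocorticoid targets and the length trend, the outcome expected was fixed before the lists or the trend were tested. Of their members, 3 of 16 glucocorticoid targets and 1 of 18 fat genes were also on fixed lists. The tests of a scaling shift, intron-retaining RNA, the tubule share, fast immediate early genes and clock phase were chosen after the result was seen, and so were the genes named in this part.

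More liver and fat genes than those on the fixed lists shared the positive sign. On a second list of 22 liver genes, 21 had a positive sign and 15 of these an unadjusted p under 0.05 in the authors' deposited table. Log2 fold changes in the authors' deposited table were 2.25 for the urea cycle enzyme Arg1 at 1.65 CPM, 2.21 for Cps1, another urea cycle enzyme, at 0.129 CPM and 0.70 for the vitamin D binding protein gene Gc at 20.3 CPM. On a second list of 18 fat genes, 16 had a positive sign, among them Otop1 (4.71), Cox8b (2.89) and Dio2 (1.80), which brown fat expresses, and the beta-3 adrenergic receptor gene Adrb3 (2.45) in the authors' deposited table. Outside these lists, the authors' deposited table gave 2.59 for urate oxidase (Uox) at 0.443 CPM and 1.74 for Rbp4 at 0.473 CPM, both abundant in liver, and 5.35 for the homeobox gene Meox2 at 0.0786 CPM. Their adjusted p in the authors' deposited table was 0.0675, 0.158 and 0.0583. Adjusted over 1 transcript per gene, Uox (0.0415) and Meox2 (0.0355) passed.

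Of 15 immunoglobulin constant region transcripts, the only 2 with an unadjusted p under 0.05 in the authors' likelihood-ratio test were those of Ighg2b. In the authors' deposited table the log2 fold change was 0.43 for Ighg1, -0.60 for Ighg2c, -0.13 for Ighm at 14.6 CPM and -0.41 for Igkc at 6.65 CPM, with p from 0.304 to 0.657. Of 186 transcripts of variable segments, 69 had a positive and 73 a negative sign, 5 and 10 of them with an unadjusted p under 0.05, and the light chain segment Igkv6-23 stood at -5.59 at 0.0866 CPM (adjusted p 0.173) in the authors' deposited table. The values do not show whether Ighg2b and Igkv6-23 came from the same kidneys.

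For the small positive sign of ribosomal protein and oxidative phosphorylation genes a trend with transcript length and level is a candidate explanation, since removing it took the median of their 103 members of at least 1 CPM from 0.189 to 0.0254. Against a shift of all genes by scaling, the members lay 0.11 above the median of genes of at least 1 CPM, and each list's median exceeded those of all 10000 random lists matched on level. Matched on level and length, ribosomal proteins lay at percentile 79.6 and oxidative phosphorylation genes at 99.8 (0.20 against a random median of 0.17). Random lists draw their genes independently and carry no correlation between members, so the percentile cannot decide whether the trend leaves a part over. The comparison with lists matched on level alone has the same limit and does not by itself exclude a scaling shift. With the trend removed, camera did not call the oxidative phosphorylation genes (adjusted p = 0.613). A different share of intron-retaining RNA stays open, as retained-intron transcripts lay below the coding transcript of the same gene in 71.5% of 3680 genes, with a median difference of -0.0415 that lies between the bounds set for either outcome. What made fold changes follow length was not tested, and an effect of quinolinic acid stays open.

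Adipocyte genes, mostly under 1 CPM, and liver genes shared a large positive sign, and the liver call stayed among genes of at least 1 CPM (adjusted p = 0.00706). Attached fat and liver RNA in some libraries may account for it, as the second fat list had a median of 0.92 and the second liver list one of 0.97, both above the bound of 0.5 fixed beforehand. The second lists show that more such genes share the sign. They cannot tell admixed RNA from expression by kidney cells, and the sizes of the differences were not compared with levels in liver or fat. A different share of tubule RNA would move other markers alike, but the adipocyte median lay 1.62 above the highest median, 0.20, of the endothelial, macrophage, smooth muscle, fibroblast and erythroid lists. It also lay above those of urothelium (0.58), nervous tissue (0.47) and adrenal gland (0.29). The liver median lay 0.93 above 0.20, short of the bound, which was set after the result was seen. Even so, the lower quartile of the liver list, 0.55, lay above the upper quartile of each of the same 5 lists, at most 0.34. These quartiles go against a different tubule share for the liver list. They were compared after the bound was missed, so they do not decide it. Urothelial (0.84) and nervous tissue (0.93) genes had higher upper quartiles, with only 3 and 4 members at 1 CPM or more. The kidneys carried 9 of the 18 second fat genes and 10 of the 22 second liver genes at 1 CPM or more, and the most abundant of each, Pck1 (0.18 at 749 CPM) and Azgp1 (0.04 at 52.0 CPM) in the authors' deposited table, have a baseline that would hide a small admixture. A difference between the groups in the expression of these genes by kidney cells stays open as untested, and the values do not show whether 1 kidney or several carried the signal.

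Immediate early genes leaned to the positive side with Dusp1. Handling at harvest cannot be told apart from an effect of treatment, since the 8 fast genes, with a median of 0.29, all come from the immediate early list itself and restate its sign. Glucocorticoid exposure stays open as well, as the 16 targets had a median of 0.23, between the bounds set for either outcome. Their unadjusted camera p was 0.000431, and 0.00216 with the length and level trend removed, which met the bound set for camera. Tsc22d3 stood at 0.63 and Fkbp5 at 0.16 in the authors' deposited table. Another clock phase at harvest was not decided either, as the 3 genes in phase with Arntl (median -0.27) and the 8 opposite to it (0.18) all come from the clock list seen before. Times of harvest per mouse were not used here, so these explanations and quinolinic acid itself remain possible.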
